A study of Mus musculus with 6 samples.

How the data were processed

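Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in hematopoietic stem cells sorted from mouse bone marrow as lineage-negative, Sca-1-positive, c-Kit-positive, CD48-negative, CD150-positive cells, per the labels. There were 6 libraries: 3 labelled Dek_fl, from mice with loxP sites in both Dek alleles, and 3 labelled Dek_cKO, from such mice that also carried Tie2-Cre, a transgene in which control DNA of the Tek (Tie2) gene drives the Cre recombinase in blood and endothelial cells. The series design text speaks of duplicates, whereas the labels give 3 libraries per group. The labels do not say whether libraries of one group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

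The authors deposited 1 peak list per library, called separately and not on pooled samples. Per the submitters' processing notes, Bowtie2, Picard and MACS2 were used with the genome build mm10. Their versions and settings, and whether reads were shifted for the Tn5 cut, are not given in the sources used here. Each deposited row holds a peak interval, a score, a fold enrichment of the summit over the local background, a −log10 p-value, a −log10 q-value and the summit position. These deposited scores and fold values are the authors' own, set within each list, and were used here only to rank, filter or describe peaks. Coordinates are 1-based on mm10.

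The lists were made in different ways. In replicates 1 and 2 of both groups the deposited score was 10 times the −log10 q-value, within 1 unit, in 100% of peaks, and the lowest −log10 q-value lay between 1.30 and 1.33. In replicate 3 of both groups the score was 10 times the −log10 p-value in 100% of peaks, with lowest −log10 p-values of 5.07 (Dek_fl) and 5.02 (Dek_cKO). Repeat-like peaks at the start of chromosome 9, between 11 and 13 per library in replicates 1 and 2, had no counterpart in replicate 3, nor did peaks with a −log10 p-value above 1000, of which replicates 1 and 2 had 7 or 8 each. Replicate number therefore also marks a processing batch, which holds both groups and is not confounded with genotype.

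Read counts per library are not known from the lists. The genome-wide background pileup was recovered from the fold and −log10 p-value of each list, as the Poisson mean that matched the most tied pairs of values to within 0.01 among peaks with −log10 p below 15. It was 5.04, 7.19 and 1.01 reads in Dek_fl replicates 1, 2 and 3 and 5.81, 4.60 and 0.76 reads in Dek_cKO replicates 1, 2 and 3. The match covered 42.0% to 55.4% of the tested peaks in replicates 1 and 2 and 7.79% and 10.4% in replicate 3, so the last values are the least certain. No confidence interval can be given for a called or uncalled peak, since the reads behind it are unknown, and an uncalled region is not shown to be closed.

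Peaks on chromosomes 1 to 19 and X were merged across libraries into union regions when they shared at least 1 bp, and a region counted as called in a library that had a peak in it. The annotation was the RefSeq gene table of the same build, with 49550 genes, 21627 of them protein-coding, on these chromosomes. It gives the start and end of each gene without strand, exons or UTRs. Transcription start sites, planned as the promoter positions, were therefore replaced by either annotated end of a gene: a peak is "at a gene end" when it lies within 1 kb of one. Exonic, intronic and UTR positions were not known, so regions are placed at a gene end, in a gene body or outside genes. The planned scan for 10 motifs was not run, because no genome sequence was used.

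Peak number, covered length and the share of peaks at gene ends were compared by an exact two-sided permutation test of the 20 assignments of the 6 libraries, whose smallest possible p is 0.1. Overlap between libraries was the Jaccard index of covered base pairs. Regions called in all 3 libraries of one group and none of the other were counted. For the 19683 regions called in all 6 libraries, the fold values were ranked within each library over these same regions, turned into normal scores, and compared with limma, with Benjamini-Hochberg adjustment over all regions and a threshold of 0.05. Gene lists were compared by the percent of members with a peak at a gene end (exact permutation test, adjusted over 17 lists), by camera and fry on the rank scores of 1 region per gene, and by Fisher's exact test of the genes nearest, within 50 kb, to regions called in one group only. The 17 lists hold 297 members, of which 296 matched the annotation by symbol, and were fixed, like the tests, the alternatives and the rule for named genes, before the data were examined.

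The text names Dek, Akt1, Akt2, Mtor, Ncor1 and Hdac3 (some genes covered by the rule are not reported here); per direction, up to 10 gene-end regions past the rank test's threshold with 3 distal ones or, where fewer than 10 passed, those that passed and the smallest p up to 5, as values that did not pass; up to 8 gene-end regions per direction called in 3 libraries of one group and 0 of the other, with 2 distal regions; list members that differed by 2 or 3 libraries; and the 3 regions of highest mean percentile. The Tek peaks were singled out after their values were seen.

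Libraries of the 2 groups share replicate numbers. Deviations from the group means of the rank scores correlated at 0.27, 0.52 and 0.74 within the numbers 1, 2 and 3, each above 0.1, so the number was kept as a block in a second fit. The correlations of Dek_fl replicate 1 with Dek_cKO replicate 2 (0.31) and of Dek_fl replicate 2 with Dek_cKO replicate 1 (0.57) were as high, so the numbers carry the processing batch and do not single out pairs within it.

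The alternatives fixed beforehand were −log10 q thresholds of 5 and 10, equal-length lists of the 23809 peaks of smallest p in each library, summit windows of 250 bp either side, overlap by 50% of the shorter peak, gene ends within 2.5 kb, genes within 100 kb, a criterion of at least 2 of 3 libraries, ranks by p, regions called in at least 5 libraries, no regions over 5 kb, array weights, quantile-normalized fold values, an estimated inter-gene correlation, the replicate block, and each library left out in turn. Several choices were revised after their outcomes were seen: gaps in percentile between the groups were moved from deposited to equal-length lists, the spread used for library overlap was redefined as the SD of same-batch Jaccard indices, the count of separated gene lists was dropped for replicate 3 alone, and an interval criterion was added to a test of the Tek peaks. Alternatives chosen after seeing the data were a threshold common to all lists (−log10 p of at least 5.07 and −log10 q of at least 2.83), fits within each processing batch, a batch term, and the block combined with ranks by p.

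The counting of group-only regions was tested on simulated data by planting 200 regions per group in the real lists, and all 200 were recovered in each direction. They were planted in every library of a group and away from all real peaks, so this checks the counting only. The rank test was tested on 19683 simulated regions with the real batch means and residual SDs and 200 planted shifts. Without the block it recovered 0% of shifts of 1 normal-score unit, 28% of shifts of 2, 64% of shifts of 3 and 88% of shifts of 4, with 0 calls elsewhere. With the block it recovered 0%, 68%, 88% and 94% of the same shifts, with 3 calls elsewhere. With the batch term it recovered 10%, 78%, 96% and 96%, with 4 calls elsewhere. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.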

Results

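ATAC-seq peak lists were analysed for hematopoietic stem cells of mice with a floxed Dek gene (3 libraries labelled Dek_fl) and of such mice that also carried Tie2-Cre (3 libraries labelled Dek_cKO). Dek encodes a chromatin-bound nuclear protein, and the series title names its part in the accessibility of stem cell chromatin as the subject. The lists labelled Dek_fl held 52451, 71555 and 23813 peaks in replicates 1, 2 and 3, and the lists labelled Dek_cKO held 70756, 73173 and 27170. Both replicate 3 lists were made with another threshold and at a lower background pileup, of 1.01 and 0.76 reads against 4.60 to 7.19 reads in the other 4 libraries.

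**Figure D1:**
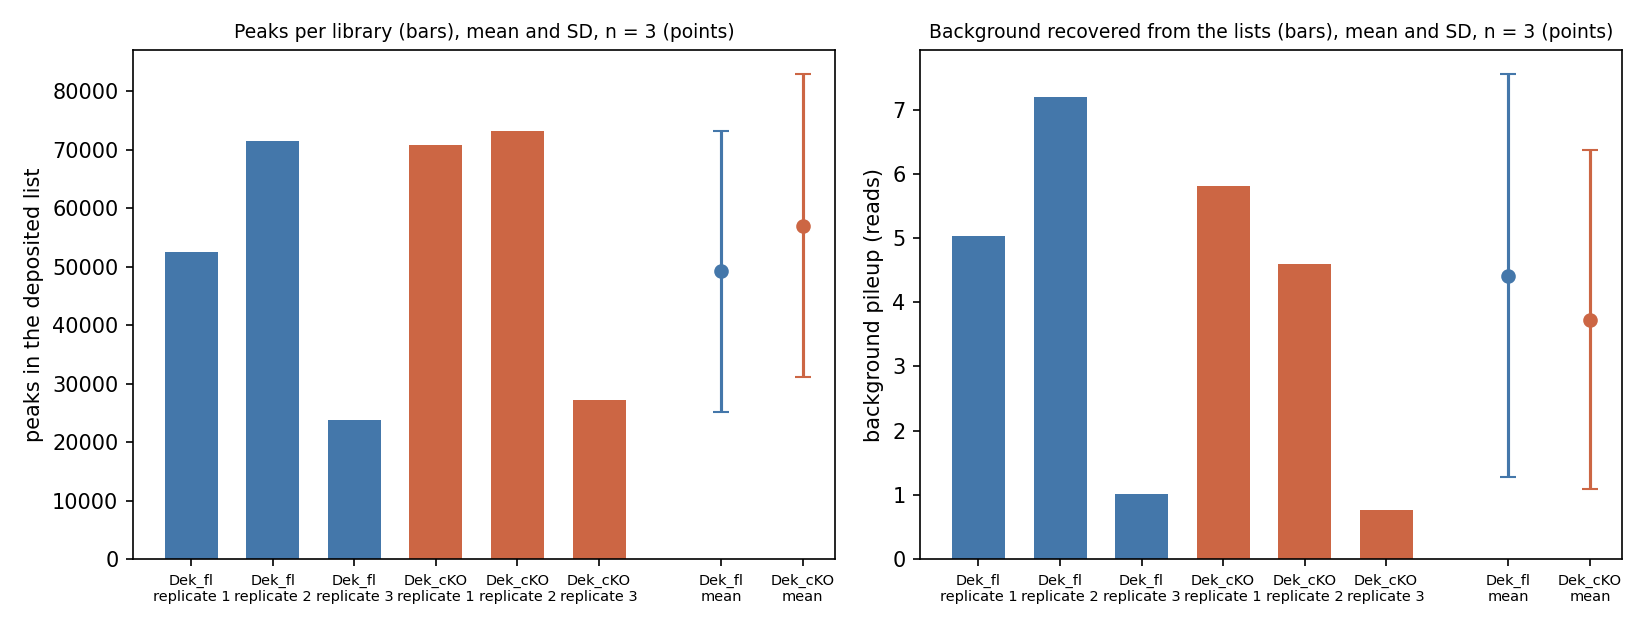
Left, number of peaks in the deposited list of each library; right, background pileup in reads recovered from each list; bars are single libraries and points are group means with SD (n = 3). Both replicate 3 libraries are the lowest of their group in both panels, with 23813 and 27170 peaks and pileups of 1.01 and 0.76 reads.

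The gene targeted in the mice was examined first. Dek lies on chromosome 13 from 47084767 to 47107530 (mm10, gene ID 110052), and a region at one of its ends, from 47104846 to 47107066, was called in all 6 libraries. Its fold over background was 4.13, 4.39 and 10.8 in Dek_fl replicates 1, 2 and 3 and 5.13, 4.26 and 10.1 in Dek_cKO replicates 1, 2 and 3. The only other peak within 5 kb of the gene, from 47080709 to 47081462 in the body of the neighbouring Kdm1b, was called in Dek_fl replicate 2 alone. The rank score of the gene-end region differed by -0.29 (cKO minus fl, SE 0.59, n = 3 per group), which did not pass the limma test (adjusted p = 1.0). It turned to 0.28 without Dek_fl replicate 3 and to 0.13 without Dek_cKO replicate 2. The floxed part of Dek is not given in the sources used here, so a peak at a gene end does not check the genotype of a library.

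A difference between the groups was seen at Tek, which encodes the angiopoietin receptor Tie2 of stem and endothelial cells and supplies the control DNA of the Tie2-Cre transgene. Tek (gene ID 21687) lies on chromosome 4 from 94739086 to 94874976. All 3 libraries labelled Dek_fl had a wide peak around the lower end of the gene, from 94737560 to 94739587 in replicate 1, 94737578 to 94739587 in replicate 2 and 94737716 to 94739534 in replicate 3, with −log10 p of 260, 576 and 56.6. They also had a peak in the gene body, between 94745330 and 94746933, 6244 to 7847 bp from that end, with folds of 9.20, 9.40 and 11.9 and −log10 p of 231, 435 and 45.9. The libraries labelled Dek_cKO, which by their label carry the transgene, had no peak in the gene body and had peaks with lower −log10 p at the gene end, of 32.9, 20.5 and 8.59, from 94738953 to 94740256, 94738664 to 94739932 and 94739066 to 94739835 in replicates 1, 2 and 3. Folds at the gene end were closer, at 7.87, 8.19 and 8.72 in Dek_fl replicates 1, 2 and 3 and 7.56, 5.98 and 5.87 in Dek_cKO replicates 1, 2 and 3. By percentile of fold within its list, Dek_cKO replicate 1 (81.6) lay above Dek_fl replicate 3 (60.2). Their summits lay 405 to 534 bp inside the gene against 46 to 197 bp in the libraries labelled Dek_fl.

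**Figure D2:**
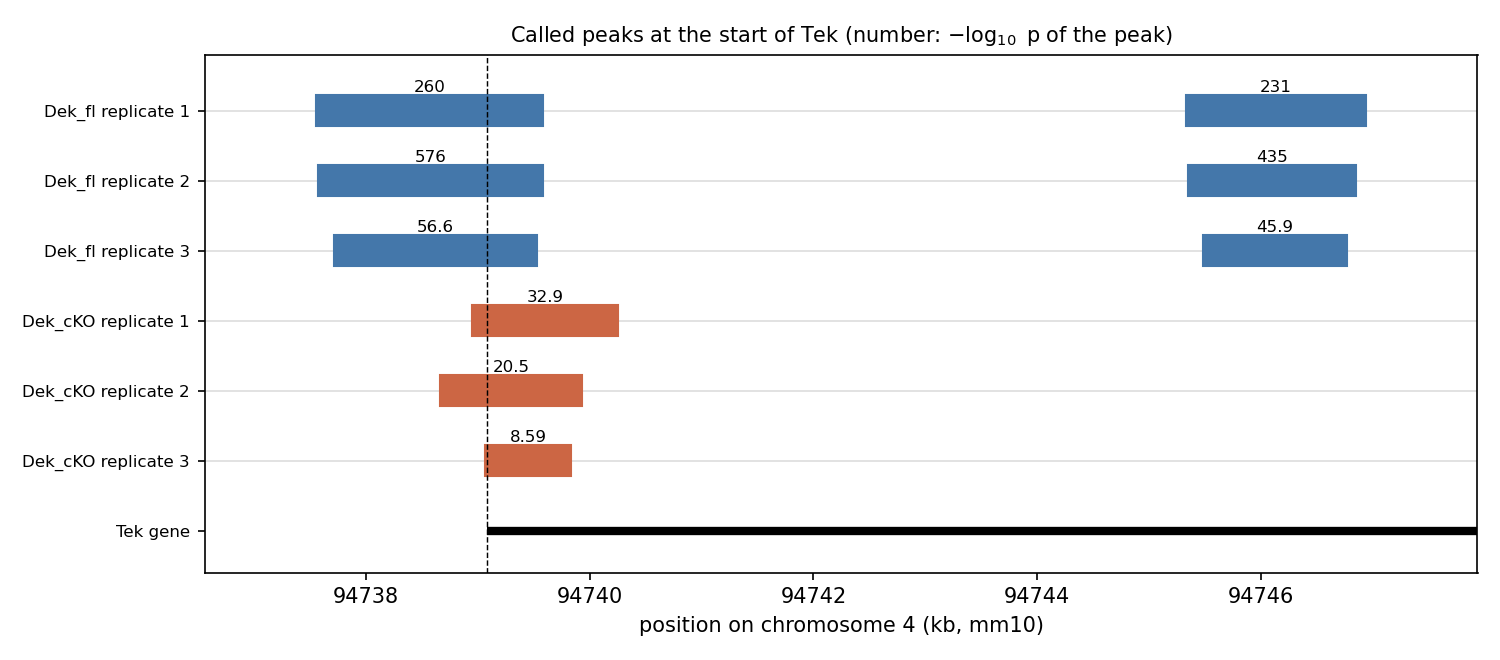
Peaks called in each of the 6 libraries at the lower end of Tek on chromosome 4 (position in kb, mm10); boxes are peaks, the number above each is its −log10 p, the dashed line is the annotated end of the gene at 94739086 and the black bar is the gene. The gene-body peak is present in the 3 libraries labelled Dek_fl and in none of the 3 labelled Dek_cKO.

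Because the Tek peaks were strongest in the libraries whose labels name no Tie2-Cre transgene, every direction below is between libraries as labelled. A direction drawn from the labels would turn round if the labels were exchanged. In equal-length lists of 23809 peaks, gaps were taken in percentile of −log10 p, not of fold, with an uncalled region set to 0. The lowest percentile among the libraries labelled Dek_fl exceeded the highest among those labelled Dek_cKO by 87.4 points at the Tek gene end. At the gene-body peak the gap was 81.8 points, and these were the 2 largest gaps toward Dek_fl of all regions. Neither element was left in any Dek_cKO list of that length. The gap at the gene end owes much to this cut: the peaks of Dek_cKO replicates 1 and 3 ranked 24661 and 24986 by p, just beyond it. In the deposited lists the percentiles of −log10 p at the gene end were 99.9, 99.98 and 87.4 in Dek_fl replicates 1, 2 and 3. In Dek_cKO replicates 1, 2 and 3 they were 65.1, 51.6 and 8.03. The next region, at an end of Plekha7 on chromosome 7, had a gap of 24.5 points, and the largest gap toward Dek_cKO was 28.5 points, near Pstpip1 on chromosome 9. The gene-body peak was called in 3 and 0 libraries also at −log10 q of at least 10. Of the other 9 splits of the libraries 2 held a region with a larger gap. These were 99.9 points near Atrnl1 (chromosome 19, 58113288 to 58113599) and 97.6 points on chromosome 9 from 3020473 to 3021001. Both of these splits set the 2 replicate 3 libraries on one side, and the latter region lies among repeat-like peaks that both replicate 3 lists lacked. In the other 5 splits with a replicate 3 library on each side, the largest gaps were 24.2 to 34.7 points. The gap was chosen as a measure after the Tek peaks had been seen, and was moved to the equal-length lists after a first computation in the deposited lists, where 3 of the other 9 splits held a larger gap than the 81.7 points of the genotype split. These 3 also set both replicate 3 libraries on one side, and the largest gaps of the 5 splits that did not were 28.1 to 50.3 points.

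The amount of called chromatin was compared between the groups. The libraries labelled Dek_cKO held 57033 ± 25890 peaks (SD, n = 3) and those labelled Dek_fl 49273 ± 24029. Each Dek_cKO list was longer than the Dek_fl list of the same replicate number. These numbers do not single out pairs within a batch, and Dek_cKO replicate 1 (70756) held fewer peaks than Dek_fl replicate 2 (71555). The log2 ratio of geometric means was 0.22 on chromosomes 1 to 19 and X, smaller than the spread between replicates (exact permutation test, two-sided, p = 0.60, where 0.1 is the smallest possible). Covered length was 50.4 ± 30.0 Mb (SD, n = 3) against 44.6 ± 30.1 Mb, a log2 ratio of 0.19 (exact permutation p = 0.80). Within replicates 1 and 2 the log2 ratios were 0.23 for both peak number and covered length, and within replicate 3 they were 0.19 and 0.11. Without Dek_fl replicate 3, Dek_cKO replicate 1 or Dek_cKO replicate 2 they turned to -0.24, -0.0038 and -0.028 for peak number and -0.46, -0.19 and -0.13 for covered length.

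Peaks lay at gene ends in 26.5%, 21.5% and 42.9% of cases in Dek_fl replicates 1, 2 and 3 and in 21.5%, 21.4% and 38.4% in Dek_cKO replicates 1, 2 and 3, against 7.92% to 8.54% when the peaks were shifted by 10 kb. The groups differed by -3.23 percentage points (exact permutation p = 0.50, two-sided, n = 3 per group), by -2.59 points within replicates 1 and 2 and by -4.51 points within replicate 3. Taken over equal-length lists, the shares were 43.4% ± 0.36 (SD, n = 3) for Dek_fl and 42.6% ± 1.41 for Dek_cKO, and leaving out Dek_fl replicate 3 turned the difference in the deposited lists to 3.07 points.

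Merging all peaks gave 84592 regions, of which 19683 (23.3%) were called in all 6 libraries. Of these shared regions 49.8% lay at gene ends, 28.1% in gene bodies and 22.1% outside genes, whereas 10.0% of the regions called in 1 to 5 libraries lay at gene ends. The 3 regions with the highest mean percentile of fold lay at an end of the zinc finger gene Zfp729a (chromosome 13, 67636928 to 67638402), in the body of Zc3h7a (chromosome 16, 11143907 to 11144306) and at an end of Gm6712 (chromosome 17, 17293360 to 17295074), each called in all 6 libraries. Covered bases overlapped with a mean Jaccard index of 0.62 between libraries of one genotype label and one processing batch (2 pairs, 0.54 and 0.70), 0.64 between the genotype labels within a batch (5 pairs), 0.23 between batches within a label and 0.23 between both. Overlap within labels minus overlap between them was -0.096 over all pairs and -0.019 within replicates 1 and 2.

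Regions called in all libraries of one group and none of the other were few. There were 88 for Dek_cKO, 7 at gene ends, 45 in gene bodies and 36 outside genes, and 3 for Dek_fl, all in gene bodies, among 84592 regions. Of the 7 gene-end regions, 6 lay at Upf1 with Cers1 and Gdf1 (chromosome 8, 70330179 to 70331187), Ftdc1 (chromosome 16, 58617130 to 58617777), Pkm with Gramd2 (chromosome 9, 59678466 to 59678885), Clec3a (chromosome 8, 114418608 to 114419339), Il17ra (chromosome 6, 120483115 to 120483694), and Serpinb10 (chromosome 1, 107528133 to 107528966). The last lay at Frmd8 (chromosome 19, 5850035 to 5850424). Only the regions are particular to Dek_cKO for most of these genes: of the 10, Clec3a and Serpinb10 had no peak at either end in a Dek_fl library, and the other 8 had one at some end in 2 or 3 Dek_fl libraries. Upf1 acts in nonsense-mediated RNA decay, Pkm encodes pyruvate kinase and Il17ra an interleukin receptor. These were weak peaks: the region at Upf1 had folds of 4.01, 3.83 and 5.93 and that at Il17ra 2.86, 2.56 and 4.14 in Dek_cKO replicates 1, 2 and 3. By mean percentile of fold, the highest distal one lay 14679 bp from Prrg4 (chromosome 2, 104864224 to 104864879). The next lay in the body of Lyn, a Src-family kinase (chromosome 4, 3766169 to 3766891), with folds of 4.55, 5.54 and 8.61. For Dek_fl the highest by that measure were the Tek gene-body peak and a region in Fam178b (chromosome 1, 36630127 to 36630584), the latter with folds of 2.91, 2.69 and 7.48.

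In equal-length lists 40 regions were called in the libraries labelled Dek_cKO only and 72 in those labelled Dek_fl only, so the direction turned. In replicates 1 and 2 alone the counts were 2555 and 282, or 1131 and 947 in equal-length lists, and in replicate 3 alone 6148 and 2864, or 3974 and 4016. Single libraries also moved the Dek_cKO-only and Dek_fl-only counts, to 136 and 275 without Dek_fl replicate 3, 193 and 7 without Dek_cKO replicate 1 and 184 and 13 without Dek_cKO replicate 2. Without Dek_cKO replicate 3 there were 2492 Dek_cKO-only regions, without Dek_fl replicate 2 there were 753, and without Dek_fl replicate 1 there were 18 Dek_fl-only regions. In equal-length lists the regions at Upf1, Ftdc1, Il17ra, Frmd8, Lyn and Prrg4 were called in 1 Dek_cKO library each and those at Pkm, Clec3a and Serpinb10 in 0. At −log10 q of at least 10, those at Ftdc1, Pkm, Clec3a and Serpinb10 were called in 0 Dek_cKO libraries and that at Il17ra in 1. Those at Upf1, Frmd8 and Prrg4 were called in 2 and that at Lyn in all 3, each with 0 Dek_fl libraries. The Dek_fl-only region in Fam178b was called in 0 libraries at that threshold. In the equal-length lists the Tek gene-body peak was called in all 3 Dek_fl libraries and the region in Fam178b in 1.

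**Figure D3:**
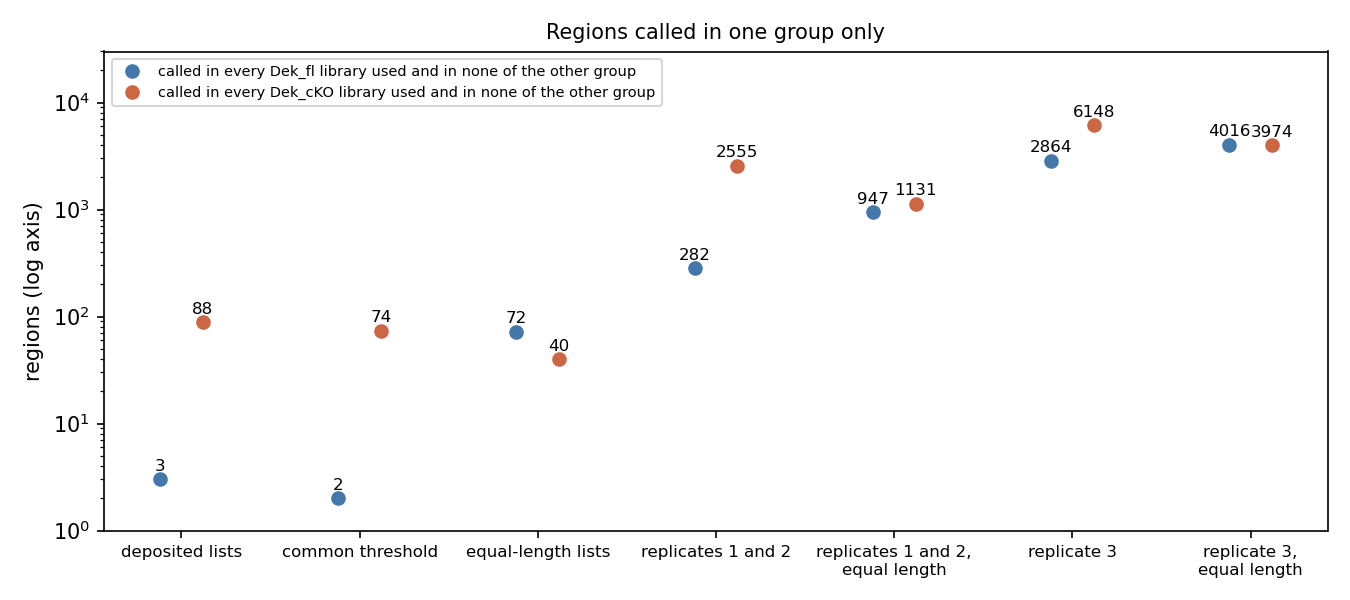
Number of regions (log axis) called in every library of one group used and in none of the other, for the deposited lists, a common threshold, equal-length lists, and the same within replicates 1 and 2 and within replicate 3. The excess for Dek_cKO in the deposited lists, 88 against 3, is 40 against 72 in equal-length lists.

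Changes in rank among the 19683 shared regions were then tested. By limma, 0 regions ranked higher and 0 lower in the libraries labelled Dek_cKO at adjusted p under 0.05, with 68 and 19 at an unadjusted p under 0.05. These are far fewer than the share of 0.05 that would reach it without any difference. The fit was therefore conservative here, and its 0 calls are weak evidence of no change. The gene-end regions of smallest p that were higher without passing were those of Marveld2, a tight junction gene (rank score difference 1.68, SE 0.44), Nbeal2 with Nradd (1.13, SE 0.37), the proteasome gene Psmb2 (1.09, SE 0.38), Cmss1 with Tmem30c (1.01, SE 0.36) and the ribosomal protein gene Rps10 (0.81, SE 0.29). Those lower without passing were Tek (-1.30, SE 0.44), Rictor, which encodes a subunit of the mTORC2 complex (-0.89, SE 0.32), Vezf1 (-0.76, SE 0.29), Rbpms (-0.89, SE 0.35) and Il1rapl2 (-1.02, SE 0.41). All 10 had an adjusted p of 1.0 by limma.

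With the replicate number as a block, 1 region ranked higher and 0 lower (585 and 289 at an unadjusted p under 0.05). The region at an end of Marveld2, on chromosome 13 from 100593276 to 100594997, rose from a mean score of 0.87 to 2.55, a difference of 1.68 (SE 0.30), with a limma adjusted p = 0.038 and a higher score in 3 of 3 pairs. With a term for the processing batch in place of the replicate number, Marveld2 did not pass (limma adjusted p = 0.98) and 0 regions were called higher or lower (545 and 302 at an unadjusted p under 0.05). In this fit and in the blocked one, regions at an unadjusted p under 0.05 also stayed below a share of 0.05. Their larger counts are thus no excess. Tek did not pass with the replicate block (limma adjusted p = 0.15) or with the batch term (limma adjusted p = 0.98). When the regions were ranked by p in the blocked fit, a combination chosen after seeing the data, the Tek gene-end region was lower, by -4.28 (SE 0.37, limma adjusted p = 0.0051), and Marveld2 did not pass. Leaving out the pair of replicate 1, 2 or 3 from the blocked fit gave 2, 16 and 7 regions ranked higher and 3, 0 and 0 ranked lower. In simulations the fit without the block recovered 0% of planted shifts of 1 unit and 28% of shifts of 2 units, and with the batch term 10% and 78%, so most shifts of the size seen at Rictor or Psmb2 would be missed by these fits.

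Genes of AKT and mTOR signalling, which controls growth and metabolism, were accessible in nearly every library. Of 27 members, 25 had a peak at a gene end in all 6 libraries, and the mean share was 97.5% ± 2.1 (SD, n = 3) for Dek_fl and 97.5% ± 4.3 for Dek_cKO, a difference of 0 percentage points (exact permutation p = 1.0, 0.1 being the smallest possible), with 1.85 points within replicates 1 and 2 and -3.70 within replicate 3. Rps6kb2 was called in 3 Dek_fl and 2 Dek_cKO libraries. The rank score difference was -0.44 (SE 0.32) at Akt1, -0.10 (SE 0.34) at Akt2, and -0.11 (SE 0.45) and 0.25 (SE 0.47) at the 2 ends of Mtor, none past the threshold. The last region also lies at an end of the neighbouring gene Exosc10, and it stood for Mtor in the list tests on ranks. Without Dek_fl replicate 3 the values at Akt2 and the ends of Mtor turned to 0.038, 0.30 and -0.31. Without Dek_cKO replicate 1 those at Akt2 and the first end of Mtor turned to 0.051 and 0.086, and without Dek_cKO replicate 2 the latter turned to 0.014. By limma 0 members passed, adjusted over all regions or adjusted over the list alone (1 at an unadjusted p under 0.05). For the list of 25 ranked members, camera gave a raw p = 0.043 toward lower ranks in Dek_cKO, a median difference of -0.072 and an adjusted p = 0.43, or an adjusted p = 0.98 with an estimated correlation.

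Corepressor and histone deacetylase genes are of interest because such complexes close chromatin. Their list also held the histone acetyltransferase genes Ep300, Crebbp, Kat2a and Kat2b, which act the other way, and it did not separate the groups either. Of 15 members 12 had a gene-end peak in all 6 libraries, with means of 93.3% ± 11.5 (SD, n = 3) for Dek_fl and 95.6% ± 7.7 for Dek_cKO. Rank score differences were smaller than their SE, from the fit without the block, at Ncor1 with Pigl (-0.12, SE 0.30) and Hdac3 with Fchsd1 and Rell2 (-0.18, SE 0.32). Paired by replicate number, the Dek_cKO score was higher in 1 pair at Ncor1 and in 0 at Hdac3, where neither passed with the block. Kat2b had a gene-end peak in 2 Dek_fl and 3 Dek_cKO libraries, although the merged region there was called in all 6. Cell cycle genes were called at 96.0% in both groups and mitochondrial genes at 95.2% in both, the latter with 20 of 21 members in all 6 libraries. Housekeeping genes stood at 93.9% in both, immediate early genes at 93.8% and 95.8%, apoptosis and DNA damage genes at 90.0% and 88.3%, and interferon genes at 86.7% and 84.4% in Dek_fl and Dek_cKO. In the apoptosis list, Mcl1, which protects stem cells from apoptosis, had a gene-end peak in 2 Dek_fl and 0 Dek_cKO libraries. These were among the weakest peaks of their lists (percentiles of fold 0.018 and 0.105), and equal-length lists gave 1 and 0. Their region, from 95663769 to 95664780, lies outside the gene, beyond its upper end at 95663179. Without strand it is not known whether transcription starts at that end, so the region is not shown to be a promoter.

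Stem cell and quiescence genes had a peak at a gene end in 77.1% ± 25.4 (SD, n = 3) of 35 members for Dek_fl and 80% ± 22.3 for Dek_cKO (exact permutation p = 0.80). The 16 members with such a peak in all 6 libraries included Meis1, Hoxa9, Runx1, Tal1, Kit and Gfi1, regulators or receptors of stem cells. Gata2, Erg and Fli1 had a peak within 1 kb of an end in 2 libraries of each group. Mecom and Hlf had one in 2 Dek_fl and 3 Dek_cKO libraries, and Cdkn1a in none. The merged regions at the ends of Mecom and Fli1 were still called in all 6 libraries, and that of Erg also in Dek_fl replicate 3, by peaks beyond 1 kb. Of 18 ranked members 0 passed by limma, adjusted over all regions or adjusted over the list alone (1 at an unadjusted p under 0.05), and 1, Tek, passed when adjusted over the list alone with the replicate block, with the batch term or ranked by p. In equal-length lists the shares were 54.3% ± 4.9 (SD, n = 3) and 55.2% ± 8.7.

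Lists of other lineages had gene-end peaks in both groups. Myeloid genes had shares of 52.6% ± 18.98 (SD, n = 3) for Dek_fl and 66.7% ± 16.9 for Dek_cKO, a difference of 14.0 percentage points (exact permutation p = 0.50, adjusted p = 1.0). The Dek_cKO share was higher in each replicate number, at 78.9%, 73.7% and 47.4% against 57.9%, 68.4% and 31.6%, as was that of T and NK cell genes, at 55.6%, 61.1% and 27.8% against 50%, 55.6% and 16.7%. Paired by number, an exact test cannot go below p = 0.25. The numbers do not single out pairs within a batch, and Dek_cKO replicate 1 and Dek_fl replicate 2 had the same T and NK cell share, 55.6%. S100a8 was called in 1 Dek_fl and 3 Dek_cKO libraries, and Ly6c2 and Camp in 0 and 2, all neutrophil or monocyte genes. In equal-length lists S100a8 and Ly6c2 were called in no library and Camp in 1 Dek_cKO library. The difference was 13.2 points within replicates 1 and 2 and 3.51 points in equal-length lists. B cell genes stood at 35.7% and 50%, T and NK cell genes at 40.7% and 48.1%, erythroid genes at 38.1% and 42.9%, megakaryocyte genes at 66.7% in both, endothelial genes at 66.7% and 69.4%, stromal genes at 74.1% and 77.8%, and genes of other tissues at 19.05% and 21.4% in Dek_fl and Dek_cKO. In equal-length lists the endothelial and stromal differences turned, to -11.1 points (38.9% against 27.8%, exact permutation p = 0.20) and -3.70 points (37.0% against 33.3%), and megakaryocyte genes stood at 42.4% and 39.4%. In replicate 3 B cell genes were at 0% and 7.14%, against 35.7% to 71.4% in the other 4 libraries. Of the other 8 lists with at least 5 ranked members 0 genes passed by limma, adjusted over all regions or adjusted over the list alone (0 at an unadjusted p under 0.05). By camera, 0 of the 10 lists with at least 5 ranked members passed (1 at an unadjusted p under 0.05), also with the block, and by Fisher's exact test 0 lists were enriched near regions called in one group only. The smallest p there was 0.0078 (adjusted p = 0.27), for the 1 stem cell gene, Tek, near a Dek_fl-only region.

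**Figure D4:**
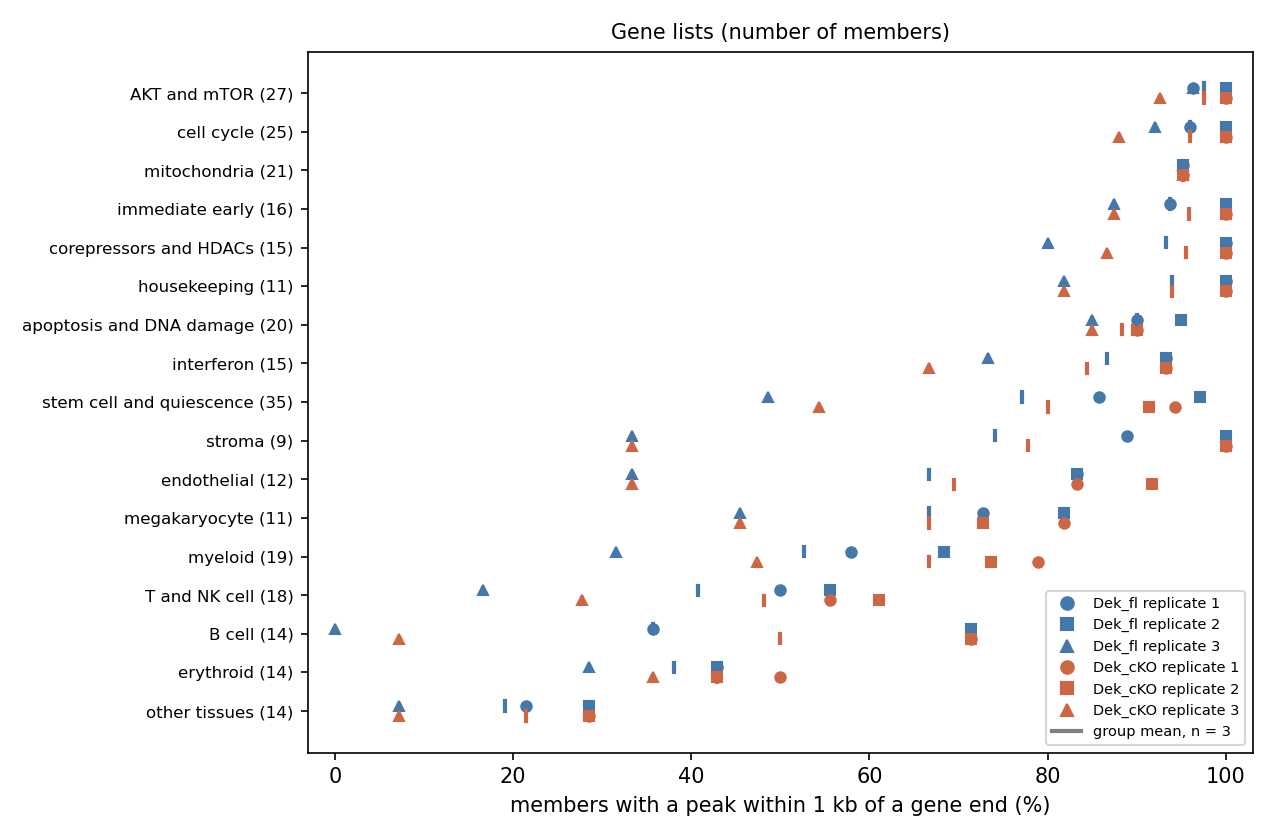
Percent of the members of each of 17 gene lists with a peak within 1 kb of a gene end, per library (symbols, by replicate number) with group means (bars, n = 3); the number of members is in parentheses. Genes of AKT and mTOR signalling lie at a mean of 97.5% in both groups and genes of other tissues at 19.05% and 21.4%.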

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

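The tests in this part, of a common threshold and of the background pileup, were chosen only after the result was seen. Chromosome Y, which no comparison used, held 25 peaks in Dek_cKO replicate 1, above the highest Dek_fl library (17 in replicate 1). These counts come from lists of 70756 and 52451 peaks, so they are not on one list length. On chromosome Y the other lists held 8 and 4 peaks (Dek_fl replicates 2 and 3) and 13 and 3 (Dek_cKO replicates 2 and 3). Outlying libraries were not tested for, since groups of 3 are too small.

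The lists of replicate 3 were shorter in both groups, by a factor of 2.63 in mean peak number. A stricter threshold in making these lists is argued against as the whole cause, since with one common threshold for all 6 lists the factor was still 2.49. A lower depth remains open and may contribute: the mean background pileup was 6.40 times higher in replicates 1 and 2, although the replicate 3 pileups rest on the fewest matching peaks (7.79% and 10.4%). The replicate 3 lists also lacked the repeat-like peaks of the other lists, for a reason not given in the sources used here. A difference between the animals of the batches was not tested.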

How the results depend on the processing

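Alternatives restricted to one processing batch, with one common threshold, with a batch term or with the block ranked by p were chosen after seeing the data. No exact permutation test of peak number, covered length, gene-end share or list share passed under any alternative, but such a test cannot go below 0.1 (0.25 with the replicate block, 0.333 for 2 against 2 libraries), so this says nothing about stability. The cause of each change below was not tested unless given.

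Leaving out 1 library at a time, the log2 ratio of peak number ranged from -0.24 to 0.69, of covered length from -0.46 to 0.89, the gene-end share difference from -8.88 to 3.07 points and lists with fully separated shares from 0 to 1. Regions called only in Dek_cKO ranged from 95 to 2492 and only in Dek_fl from 4 to 275. Covered length turned to -0.020 in equal-length lists of replicate 3. Library overlap moved to -0.019 in replicates 1 and 2 and to -0.016 in their equal-length lists.

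Dek_cKO-only and Dek_fl-only regions were 51 and 1 at −log10 q of at least 10, 40 and 72 in equal-length lists, 2695 and 291 when 2 of 3 libraries sufficed, 2555 and 282 in replicates 1 and 2, 1131 and 947 in their equal-length lists, 6148 and 2864 in replicate 3 and 3974 and 4016 in its equal-length lists; fewer libraries make the criterion easier to meet. Summit windows gave 11 Dek_fl-only regions. With the replicate block, which leaves the 88 and 3 regions as they are by construction, 2 gene lists (myeloid, T and NK cell) had differences of one sign in all pairs by number, against 0 lists separated without it. For T and NK cell genes this depends on how libraries are paired within replicates 1 and 2. In replicates 1 and 2, 1 list was separated, also with equal lengths. No such count is given for replicate 3 alone, where any difference separates 1 library from 1; it was left out after it had been computed.

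With all 6 libraries or 1 left out, the rank test called 0 regions except 1 higher with the replicate block and 1 lower with the block ranked by p, and camera called 0 lists. Leaving out a whole pair from the blocked fit gave 2, 16 and 7 regions higher and 3, 0 and 0 lower. Tek also passed adjusted over the stem cell list alone with the block, with the batch term and ranked by p; the block changed no other call. Among single regions, none of which passed, the rank difference at Mtor (start 148448058) turned to 0.11 ranked by p, with and without the block. That at its other end, shared with Exosc10, turned to -0.15 with array weights and -0.29 in replicates 1 and 2. Leaving out 1 library, these ranged from -0.45 to 0.30 and from -0.31 to 0.56, Dek from -0.81 to 0.28 and Akt2 from -0.38 to 0.051. The motif alternatives were not run. Reads per library are not known, so what depth limits was not measured. Of planted shifts of 1 unit the rank test found 0%, with or without the replicate block, and 10% with the batch term.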

Other observations

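The bounds of the Tek test by peaks of like fold were written before its percentages were seen, though the folds and p-values it uses were known. Its interval criterion and the bounds of all other tests of an explanation here were set afterwards. The equal-length lists, the rank test, camera, the replicate block and the comparison of group-only counts with other splits had been planned. Of the 84592 regions, 21701 were called in all 4 libraries of replicates 1 and 2 and in neither replicate 3 library, and 205 in both replicate 3 libraries and none of the other 4. Genes with a peak at neither end in any library numbered 6548 of 21627 protein-coding genes, and 10548 had one in all 6. In equal-length lists, 177 protein-coding genes had a gene-end peak in 2 or 3 more Dek_fl than Dek_cKO libraries and 96 the reverse, whereas in the deposited lists the numbers were 17 and 128.

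The Tek peaks of the libraries labelled Dek_fl may come from extra copies of Tek control DNA, as a Tie2-Cre transgene would bring, so the genotype labels may be exchanged, or the labelled controls may carry the transgene. Either way the libraries labelled Dek_cKO would have to lack such copies, since none of them had the gene-body peak. Copies would raise a peak and its surroundings together, so under 5% of peaks of like fold (within 5%) should have a higher −log10 p: the share was 0.042% to 3.14% for 5 of the 6 Tek peaks in these libraries, but 51.8% (837 of 1616) for the gene-body peak of replicate 3, above the 50% that had been set as the bound against this explanation. By that bound alone the explanation would be rejected, and it is left open here only because the 95% Wilson interval reaches down to 49.4%, a criterion set after the value was seen. For the gene-end peaks of Dek_cKO replicates 1, 2 and 3, 73.9%, 49.6% and 82.7% of peaks of like fold had a higher −log10 p. Depth or list length is argued against, since Dek_cKO replicate 1, at a background pileup of 5.81 reads, exceeded Dek_fl replicates 1 and 3, and all 3 Dek_cKO lists without the peak were longer than that of Dek_fl replicate 3 with it. A lower accessibility of Tek in cells without Dek, with a rank score difference of -1.30, stays open, although by that score Dek_cKO replicate 1 (0.16) lay above Dek_fl replicate 3 (0.071), because the gene-body peak followed the genotype label in all 6 libraries.

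The excess of regions called only in the libraries labelled Dek_cKO may follow from their longer lists: the ratio of Dek_cKO-only to Dek_fl-only regions was 0.56 in equal-length lists, against 88 to 3 in the deposited ones. A real gain of accessible regions stays open, since equal-length lists remove such a gain by construction; within replicates 1 and 2 the equal-length ratio was 1.19. Of the 10 splits of the 6 libraries, 7 gave at least the 91 regions of the real one, and the highest other split gave 10620. This split sets Dek_fl replicate 1 and both replicate 3 libraries, the 3 shortest lists, against the rest, and points to list length and batch as a structure of the samples. The other 5 splits with a replicate 3 library on each side gave 20, 99, 101, 16 and 37 regions. In equal-length lists these gave 94, 107, 75, 99 and 108, and the real split gave 112.

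For the rank test the real split called 0 regions, so all 10 splits called at least as many by definition. The highest other split called 51, again with Dek_fl replicate 1 and both replicate 3 libraries on one side. For gene lists by camera the real split and the highest other both called 0, in 10 of 10 splits. With 0 calls in the real split, neither comparison can decide anything. With the block, 1 of the 4 splits that part all pairs, the real one, called at least 1 region (Marveld2), and the highest other called 0. With 10 or 4 splits no share under 0.05 is possible.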
